A study of Drosophila melanogaster with 36 samples.

How the data were processed

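RNA was measured in cells sorted from the wing and haltere imaginal discs of wandering Drosophila melanogaster larvae, the epithelial sacs from which the adult wing and the small balancing haltere form. Per the labels' protocols, larvae were raised at 25 °C, total RNA was extracted with TRIZOL, and libraries were made with the Nugen Ovation Drosophila system. The cells carried a nuclear envelope GFP under a Gal4 driver, either nub-Gal4, active in the distal appendage primordium, or tsh-Gal4, active in proximal cells, and came from a y w background. The series holds 36 samples, of which the 17 ATAC-seq and 11 ChIP-seq samples were not analysed here. The 8 RNA-seq libraries form 4 groups (haltere tsh, haltere nub, wing tsh and wing nub) of 2 replicates each, assigned from the labels.

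The values deposited by the authors are raw read counts per gene, 1 library per file, for the same 17807 FlyBase gene IDs, as the whole numbers and differing totals in the files show. The submitters' processing notes name bcl2fastq, HISAT2, Bowtie2, deepTools and the dm6 build for the whole series, with no version or role. The counting tool, the annotation release, the use of strand and the handling of reads that match several genes are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical copies such as the Hsp70 genes are therefore uncertain. Of the IDs, 17710 were matched to a symbol and 97 were not, and the latter held between 0.62% and 0.71% of the counts of a library. Coordinates are those of the Release 6 assembly, of which dm6 is a build.

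Library totals lay between 15110163 and 17705451 counts in 6 libraries and were 96525031 and 92342738 in the 2 haltere nub libraries. A single read equalled 0.0662 CPM (counts scaled to the library total) in the shallowest library and 0.0104 CPM in the deepest. Floors of 3 counts and 95% intervals of ratios cover counting error only. The replicates of each group differed by more than sampling noise, with a chi-square per gene between 9 and 31.4 over genes with at least 20 reads, so that none was taken for a repeated deposit. The labels do not say whether replicates came from separate cohorts of larvae, so p-values measure the spread between these samples, which may be technical. Some ecdysone genes, picked after their values were seen, moved alike in same-numbered nub libraries of both discs. Hr3 stood at 11.84 and 20.04 CPM in haltere and 12.56 and 21.21 in wing nub replicates 1 and 2. The gene ftz-f1 rose likewise, and Hr4 and ImpE1 fell in both discs. Eip75B and Eip74EF moved opposite ways in the discs. Cohorts shared by same-numbered libraries therefore stay possible.

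Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (11198 kept, 6609 left out), libraries were scaled by TMM, and a quasi-likelihood model with robust dispersions was fitted to the 4 groups over all 8 libraries, with 4 residual degrees of freedom. The common biological coefficient of variation was 19.9%. The 5 contrasts were haltere against wing in nub cells and in tsh cells, nub against tsh cells in the wing disc and in the haltere disc, and the disc by domain interaction. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were taken from the unshrunken coefficient and the F statistic. CPM values in the text are scaled by TMM and given as mean ± SD over 2 libraries.

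A set of 25 gene lists was tested in each contrast with limma 3.58.1 (camera on voom values, a preset correlation of 0.01), adjusted over 125 tests. The lists covered distal appendage, proximal, hinge, Hox and leg disc regulators, wing genes described as repressed in the haltere, the BMP, Wnt, EGFR, Notch, Hedgehog, Hippo and JAK/STAT pathways, sensory organ genes, markers of myoblasts, trachea, hemocytes, fat body and neurons or glia, cell cycle, stress and ecdysone genes, dosage compensation, ribosomal protein and mitochondrial genes. Camera called 59 of the 125 tests, and none of them with a correlation estimated per list.

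Samples, tests, lists, the alternatives of the plan and the rule for naming genes were fixed before the data were examined. The rule named Ubx, Antp, nub and tsh, the 10 genes with the largest fold change in each direction of each comparison of 2 groups (called, at least 5 CPM on average, replicates not overlapping), the list members with the smallest adjusted p, and the 10 interaction genes with the smallest adjusted p at 5 CPM or more on average. Genes known by number only could be left to a count under this rule. Those not named in their comparison, among the 10 of either direction, numbered 3 for haltere against wing in nub cells, 8 in tsh cells, 4 for nub against tsh in the wing disc and 5 in the haltere disc. The pipeline was tested on simulated counts drawn at the real means and depths. Changed genes were taken from those of at least 5 CPM on average, so recovery below that level was not measured. Genes were drawn independently of each other, so correlation within lists was not simulated. In the simulated haltere against wing comparison of nub cells over 11198 genes, 61.2% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, with 10 of 10978 unchanged genes called. For tsh cells the shares were 58.2%, 82.1% and 98.5%, with 16 unchanged genes called. Camera at the preset correlation called a list of 20 genes raised 1.5-fold in both simulations, and also 1 list that had not been raised in the nub simulation and 0 in the tsh simulation.

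Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a stricter filter of 5 CPM, a 2-fold threshold, fits of the compared groups alone, a replicate block, removal of mitochondrial and rRNA genes, each library left out in turn, camera with an estimated correlation and fry. Added after seeing the data were thinning of every library to 15110163 counts, and 2 corrections for a trend with gene span, the latter fitted first over all tested genes and then, after that result was seen, over genes of at least 5 CPM. Fits without a library, and those of the compared groups, used the genes of the full fit. They had first been run with the filter applied again, and this was changed after the filter had been seen to pass up to 14934 genes. Both sets of counts are given.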

Results

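The data were 8 RNA-seq libraries of sorted wing and haltere disc cells, 2 from each of haltere tsh, haltere nub, wing tsh and wing nub cells. The totals were 15110163 and 17556152 counts for haltere tsh and 96525031 and 92342738 for haltere nub. They were 15583085 and 16964968 for wing tsh and 17291927 and 17705451 for wing nub. The first principal component held 45.3% of the variance and separated nub from tsh libraries in both discs. Wing tsh replicate 1 stood apart: 5186 genes lay between 1 and 5 CPM there against 1822 to 2312 in the other libraries. Its log2 CPM had a Pearson's r of 0.975 with those of replicate 2 across genes, against 0.992 to 0.997 in the other groups. These correlations rest on values that are not independent replicates.

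**Figure D1:**
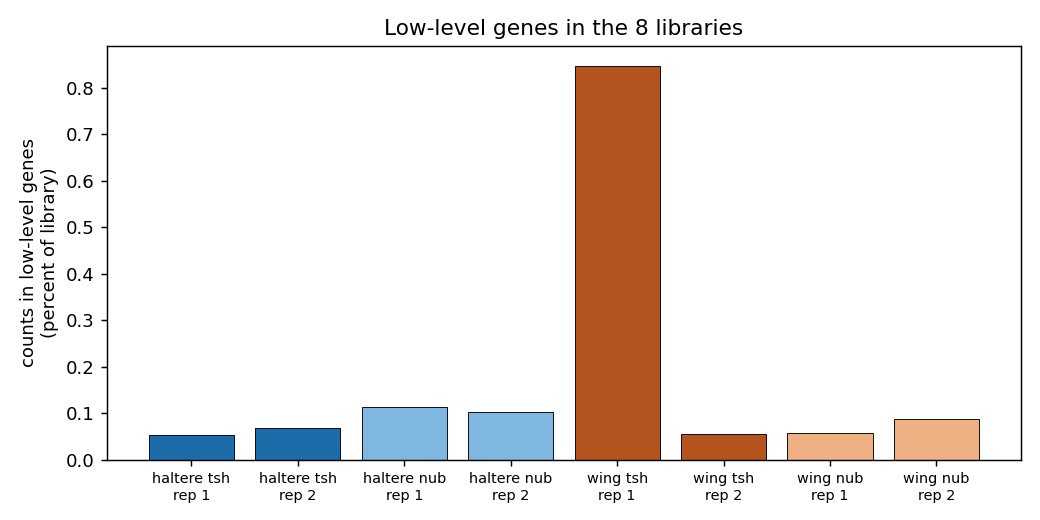
Percent of each library's counts (y axis) in the 7458 genes under 0.5 CPM on average over the 7 libraries other than wing tsh replicate 1. Each bar is 1 library, coloured by group, and wing tsh replicate 1 holds 0.848% against 0.054% to 0.114% in the others.

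The 4 genes that mark disc and domain followed the labels in every library. Ubx (3R, 16656623 to 16734426), the Hox gene of the haltere segment, stood at 794 ± 35 CPM in haltere tsh and 2746 ± 11.0 CPM in haltere nub cells. It stood at 37.1 ± 0.132 in wing tsh and 4.50 ± 3.45 in wing nub cells (SD, n = 2). Antp (3R, 6896253 to 6999228), a Hox gene of the thorax, was highest in wing tsh cells (1131 ± 187 CPM). It stood at 154 ± 4.18 in wing nub, 82.6 ± 18.1 in haltere tsh and 18.8 ± 2.17 in haltere nub cells. The driver genes separated the domains. The gene nub (2L, 12587625 to 12628135), a POU factor of the appendage, reached 1039 ± 3.27 CPM in haltere nub and 1619 ± 45.3 in wing nub cells. It was at 10.4 ± 0.0968 and 37.4 ± 1.83 in the tsh cells of the same discs. The zinc finger gene tsh (2L, 21828593 to 21837011) stood at 868 ± 41.9 and 727 ± 53.0 CPM in haltere and wing tsh cells and at 26.5 ± 4.30 and 15.5 ± 5.03 in nub cells.

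**Figure D2:**
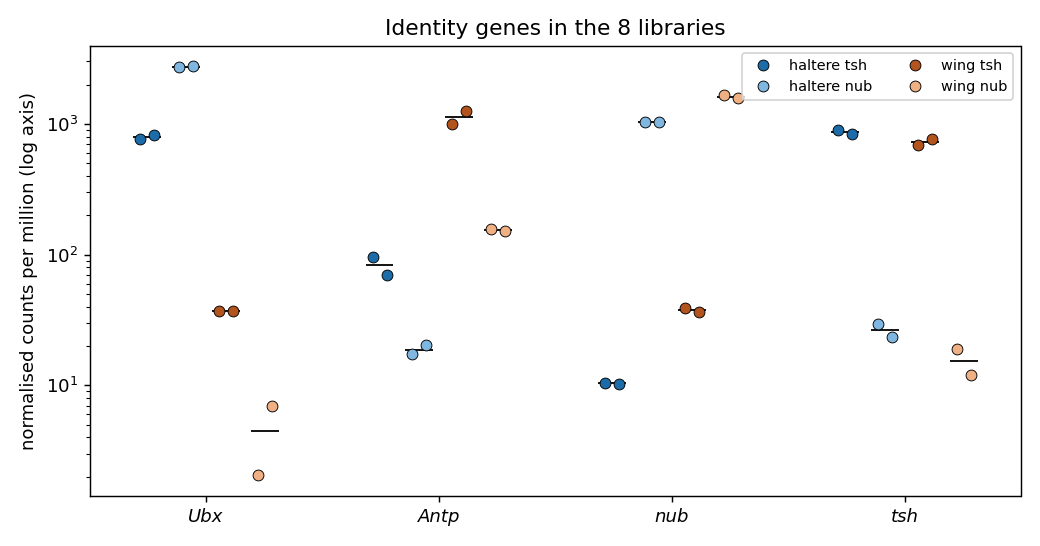
CPM scaled by TMM (log axis) of Ubx, Antp, nub and tsh. Points are the 2 libraries of each group and short lines their mean. Ubx is highest in the haltere groups, and nub and tsh part the nub from the tsh groups in both discs.

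The comparison of nub cells asked how the distal primordium of the haltere differed from that of the wing. Apart from Ubx (log2 fold change 9.24 ± 0.40 SE), the haltere cells had far less of the T-box genes Doc1 (-5.58 ± 0.15), Doc2 (-6.14 ± 0.14) and Doc3 (-4.29 ± 0.16). They also had less of ltl (-5.34 ± 0.12), the zinc finger gene opa (-4.62 ± 0.12) and ana (-4.58 ± 0.21), which encodes a secreted glial protein. Doc2 stood at 1.06 ± 0.102 CPM in haltere nub and 75.1 ± 2.23 CPM in wing nub cells. Cuticle gene Cpr12A (-4.51 ± 0.16), flap (-4.32 ± 0.27) and the homeobox gene al (-3.28 ± 0.13) were also lower in the haltere. Higher there were the serine protease gene Corin (8.30 ± 0.98, 382 ± 64.7 against 1.19 ± 1.35 CPM) and the neuropeptide receptor gene CCAP-R (7.42 ± 1.09). So were the cuticle genes Cpr92A (5.45 ± 0.96) and Ccp84Ab (5.19 ± 0.46), the immunoglobulin gene DIP-epsilon (5.29 ± 0.28) and the aquaporin gene Eglp2 (36.9 ± 2.83 against 1.16 ± 0.358 CPM). Antp (-3.03 ± 0.17) and nub (-0.64 ± 0.08) were lower and tsh (0.78 ± 0.19) higher in haltere nub cells. Cpr47Ee was higher by a ratio of 579 (95% counting interval 104 to 22900), with 1 count in the wing nub libraries. The call of CCAP-R was lost without any single library of the 2 groups, that of Cpr92A without wing nub replicate 2, and that of tsh without haltere nub replicate 1 or wing nub replicate 2.

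Distal appendage genes were lower as a group in haltere nub cells, with 8 of 15 members lower and 1 higher (8 and 2 adjusted over the list alone). The growth regulator fj (-2.52 ± 0.10), the homeobox gene Dll (-2.20 ± 0.09), the zinc finger genes salr (-2.10 ± 0.09) and salm (-1.25 ± 0.09), and bs (-1.10 ± 0.10) were below the wing level, as was the wing selector vg, whereas bi was higher (0.66 ± 0.12). The camera adjusted p of this list was 4.18e-05. It had an adjusted p = 0.194 with an estimated correlation. Of 12 wing genes described as repressed in the haltere, 7 were lower, among them knrl (-1.35 ± 0.10) and kni (-1.57 ± 0.15). The 3 higher ones included wg (1.22 ± 0.13) and ac (1.19 ± 0.16) (adjusted p = 0.00385, and adjusted p = 0.338 with an estimated correlation). Notch pathway genes were higher in 10 of 16 cases and lower in 2, led by the Notch targets E(spl)mgamma-HLH (3.16 ± 0.19) and E(spl)m4-BFM (1.90 ± 0.13) (adjusted p = 5.1e-05, and adjusted p = 0.384 with an estimated correlation). Among 12 sensory organ genes 6 were higher, such as Brd (1.69 ± 0.14), and sens was lower (-1.41 ± 0.22) (adjusted p = 0.00204, and adjusted p = 0.365 with an estimated correlation).

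Cell cycle genes were lower in haltere nub cells in 14 of 19 cases, with CycE at -0.69 ± 0.09 and stg at -0.61 ± 0.10 (adjusted p = 7.66e-07, and adjusted p = 0.365 with an estimated correlation). Ribosomal protein genes were lower in 64 of 86 cases with a median of -0.57 (adjusted p = 4.83e-23, and adjusted p = 0.396 with an estimated correlation). They held 3.15% and 3.11% of the counts of the haltere nub libraries against 3.94% to 4.58% in the other libraries. Those 2 libraries were also the deepest by a ratio of 5.22. Stress genes were higher in 14 of 22 cases and lower in 2, with the heat shock genes Hsp70Aa at 1.98 ± 0.22 and Hsp70Ba at 1.25 ± 0.14 and the cell death gene hid at -0.70 ± 0.08 (adjusted p = 0.000951, and adjusted p = 0.384 with an estimated correlation). With the gene span trend of all genes removed, 4 cell cycle and 8 ribosomal protein genes were called lower and 7 stress genes higher. The medians were then -0.47, -0.67 and 0.64, against -0.36, -0.57 and 0.76 before, while the median SE of all genes rose from 0.16 to 0.27. Mitochondrial genes were lower in 3 of 22 cases (adjusted p = 0.00976, and adjusted p = 0.341 with an estimated correlation).

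The other lists were not called by camera in this comparison. Of the Hox list only Ubx and Antp were called. Of the hinge list 3 members were higher, such as Sox15 (1.13 ± 0.09), and 4 lower, 3 of them the Doc genes. Of the 15 proximal genes 6 were higher, such as eyg (2.30 ± 0.12), and 4 lower, such as caup (-1.86 ± 0.08). Wnt genes went both ways, 7 higher and 4 lower, with Wnt4 at 2.46 ± 0.15 and Wnt2 at -2.30 ± 0.15. Compartment genes were lower in 4 of 8 cases, including hh (-1.19 ± 0.09) and en (-1.16 ± 0.12), and ptc was higher (0.78 ± 0.10). BMP genes (3 higher and 5 lower of 14) and JAK/STAT genes (2 and 2 of 9) changed both ways. EGFR genes (2 and 2 of 12), Hippo genes (0 and 3 of 14), leg disc genes (1 and 2 of 7) and ecdysone genes (1 and 2 of 17) had fewer calls. Among markers of other cells 4 of 7 tracheal genes were called (1 higher and 3 lower), with 1 of 8 myoblast, 0 of 8 hemocyte, 1 of 6 fat body and 1 of 12 neuron or glia genes. None of the 3 dosage compensation genes was called.

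The haltere nub libraries were far deeper than the others, so a separate sequencing batch cannot be told apart from tissue in any contrast with them. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2614 of 11198 genes differed, 1089 higher and 1525 lower in the haltere, and 709 of them by at least 2-fold (506 higher and 203 lower). The count was 1525 with a gene span trend over all genes removed and 3952 when only these 4 libraries were fitted. It was 1260 and 1176 without haltere nub replicate 1 or 2 and 1294 without wing nub replicate 1.

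**Figure D3:**
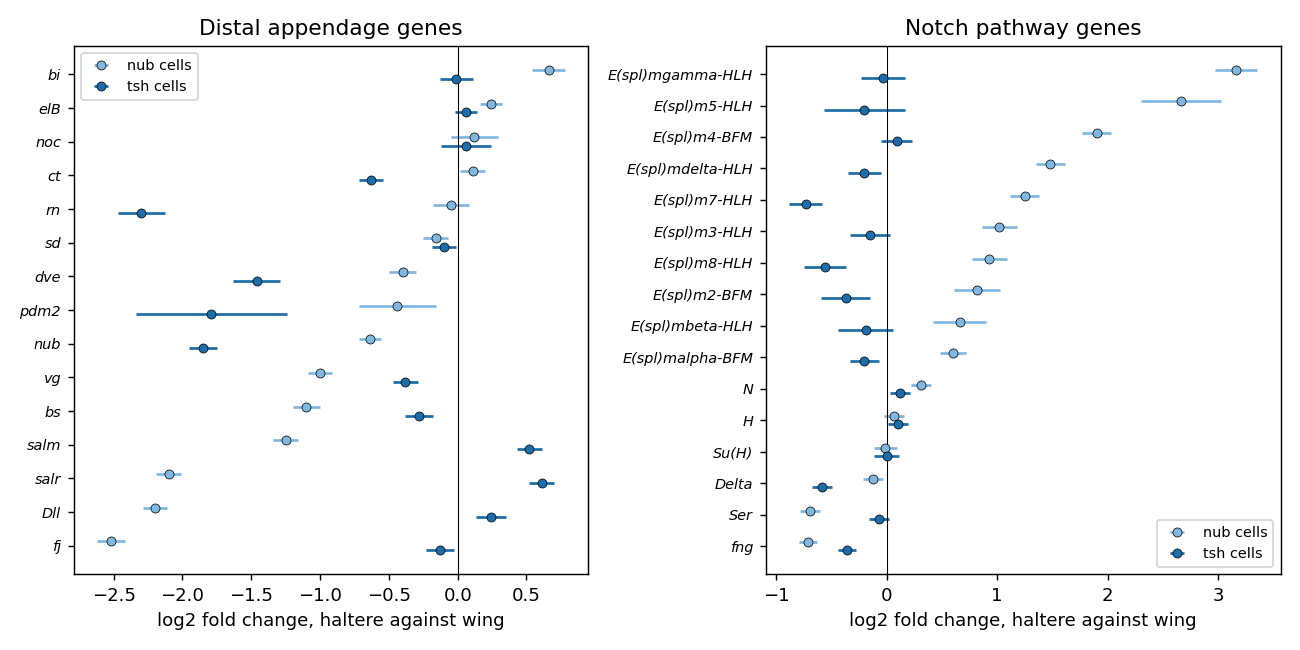
Log2 fold changes of haltere against wing (x axis, bars are SE from the edgeR fit of 8 libraries) for members of the distal appendage and Notch pathway lists, in nub cells (light) and tsh cells (dark). In nub cells fj, Dll and salr lie at or below -2.10, and E(spl)mgamma-HLH lies at 3.16.

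The comparison of tsh cells asked the same of the proximal domain. Beside Ubx (4.42 ± 0.31), haltere tsh cells had more of the cuticle gene Cpr47Ee (3.82 ± 0.28), DIP-epsilon (2.08 ± 0.20), the chitinase gene Cht5 (2.03 ± 0.09, 234 ± 15.7 against 57.0 ± 1.77 CPM), Doc3 (1.46 ± 0.16) and Cpr65Ec (1.34 ± 0.24). They had less of the cuticle gene TwdlT (-6.41 ± 0.58), ana (-5.58 ± 0.37), the cell adhesion gene Con (-4.66 ± 0.25, 1.52 ± 0.456 against 38.2 ± 0.467 CPM), the lipid carrier gene Apoltp (-4.28 ± 0.45), ltl (-3.97 ± 0.21) and Antp (-3.78 ± 0.17). Apoltp, a member of the fat body list, stood at 33.2 and 16.9 CPM in wing tsh replicates 1 and 2. That list was not called by camera, with 1 of 6 members lower and a median of -1.83. CG4607 had 0 counts in both haltere tsh libraries and was at least 120-fold lower than in wing tsh cells, against a floor of 3 counts over the group.

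Myoblast genes were lower in haltere tsh cells in 6 of 8 cases (7 adjusted over the list alone), including the muscle precursor genes zfh1 (-2.32 ± 0.25), the FGF receptor gene htl (-1.79 ± 0.32) and kirre (-1.20 ± 0.12), with a median of -1.67 (adjusted p = 6.12e-10, and adjusted p = 0.194 with an estimated correlation). Without wing tsh replicate 1, 4 of the 8 were called lower, with a median of -1.44. Proximal genes were lower in 4 of 15 cases, with eyg at -1.26 ± 0.11 and vn at -0.72 ± 0.08, and higher in 2, Dr (0.67 ± 0.11) and tup (0.66 ± 0.12) (adjusted p = 0.000171, and adjusted p = 0.384 with an estimated correlation). Among distal genes nub (-1.85 ± 0.10), rn (-2.30 ± 0.17) and dve (-1.46 ± 0.17) were lower and salr (0.61 ± 0.09) and salm (0.52 ± 0.09) higher (5 lower and 2 higher of 15, adjusted p = 0.0093, and adjusted p = 0.33 with an estimated correlation). Hinge genes were higher in 3 of 10 cases, Doc3, Sox15 (0.61 ± 0.08) and Doc2 (0.94 ± 0.14) (adjusted p = 0.0058, and adjusted p = 0.365 with an estimated correlation). No cell cycle gene of 19 was called, though 8 were higher adjusted over the list alone, with a median of 0.23 (adjusted p = 1.21e-05, and adjusted p = 0.384 with an estimated correlation). No ribosomal protein gene was called, with a median of 0.03. Camera also called the BMP, Notch, sensory organ, leg disc and ecdysone lists, all downward, with adjusted p between 0.338 and 0.609 with an estimated correlation. They had 2, 3, 2, 3 and 2 members called lower and none higher. The BMP list turned upward without wing tsh replicate 2, with a median of 0.06, and so did the distal, Notch and ecdysone lists where the filter was applied again.

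By the same test 365 genes differed, 116 higher and 249 lower in the haltere, 160 of them by at least 2-fold (22 higher and 138 lower). The raised low-level genes of wing tsh replicate 1 push values downward here, and the 2-fold counts were not recomputed without that library. DESeq2 called 720. Without wing tsh replicate 2, which leaves wing tsh replicate 1 alone in its group, the count was 1621, whereas it was 405 without replicate 1 and 177 and 234 without haltere tsh replicate 1 or 2. Without wing tsh replicate 1 the log2 fold change of Ubx stayed at 4.42, with an adjusted p of 0.0551. Cpr65Ec lost its call without any of the 3 libraries haltere tsh replicate 1 or 2 or wing tsh replicate 1.

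Within the wing disc, nub cells were set against tsh cells to describe distal and proximal identity. The domains came from different driver lines, so a difference between lines cannot be told apart from one between domains, in either disc. Distal cells had far more of y (8.79 ± 0.20, 6468 ± 789 against 14.6 ± 3.55 CPM), a pigmentation gene on the X chromosome (356509 to 361245). Also higher were peg (5.85 ± 0.14), nub (5.43 ± 0.10), the homeobox gene dve (5.43 ± 0.13), RacGAP84C (5.33 ± 0.33), nab (5.27 ± 0.18) and rn (5.22 ± 0.15), the latter a zinc finger gene of the pouch. Cyp6a17, a cytochrome P450 gene, had 0 counts in wing tsh cells and was at least 161-fold higher in wing nub cells. It also stood at 0 CPM in haltere tsh and at 9.45 ± 0.183 CPM in haltere nub cells. Vajk2 was also higher (5.57 ± 0.79), a call lost without any single library of the 2 groups. Lower in distal cells were the cuticle gene Cpr49Ac (-7.22 ± 0.57), the aquaporin gene Drip (-6.64 ± 0.31), B-H1 (-6.17 ± 0.34), dpr16 (-5.99 ± 0.33), eya (-5.91 ± 0.18), drm (-5.85 ± 0.20) and tio (-5.79 ± 0.16).

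The domain lists parted strongly in the wing disc. Of 15 distal genes 13 were higher in nub cells, including Dll (4.04 ± 0.11) and bs (2.44 ± 0.10), and ct was lower (adjusted p = 4.68e-21, and adjusted p = 0.0591 with an estimated correlation). Of 15 proximal genes 14 were lower, including tup (-5.74 ± 0.19) and eyg (-2.95 ± 0.13) (adjusted p = 1.67e-22, and adjusted p = 0.194 with an estimated correlation). Compartment genes were higher in 6 of 8 cases, with en at 1.64 ± 0.13 (adjusted p = 9.97e-06, and adjusted p = 0.194 with an estimated correlation). EGFR genes were higher in 7 of 12 cases, with rho at 1.89 ± 0.12 (adjusted p = 1.24e-05, and adjusted p = 0.33 with an estimated correlation), and Wnt genes in 9 of 16 and lower in 2, with Notum at 1.60 ± 0.09 (adjusted p = 0.000126, and adjusted p = 0.338 with an estimated correlation). Leg disc genes were lower in 6 of 7 cases, with C15 at -5.14 ± 0.28, while al was higher (2.35 ± 0.13) (adjusted p = 0.00192, and adjusted p = 0.292 with an estimated correlation). Myoblast genes were lower in 6 of 8 cases, with stumps at -2.93 ± 0.22 (adjusted p = 0.000465, and adjusted p = 0.247 with an estimated correlation). Tracheal genes were lower in 5 of 7 cases, with dysf at -5.68 ± 0.23, whereas trh was higher (3.50 ± 0.15) (adjusted p = 0.00976, and adjusted p = 0.33 with an estimated correlation). Hox genes were lower in 4 of 7 cases, Antp (-2.88 ± 0.17), Ubx (-3.03 ± 0.37), lab and Abd-B (adjusted p = 0.00135, and adjusted p = 0.365 with an estimated correlation). Without wing tsh replicate 1, 2 of the 7 were called. Camera also called the repressed wing gene, Notch, cell cycle, ribosomal protein and mitochondrial lists upward and the JAK/STAT, stress and ecdysone lists downward, with adjusted p between 0.338 and 0.75 with an estimated correlation. Of the ribosomal protein genes 3 of 86 were called, and the list turned downward, to a median of -0.08, without wing tsh replicate 1.

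By the same test 1549 genes differed, 667 higher and 882 lower in nub cells, and 730 by at least 2-fold (164 higher and 566 lower). Here too the low-level genes of wing tsh replicate 1 push values downward, and the 2-fold counts were not recomputed without it. The count was 1595 without wing tsh replicate 1, 2718 without wing tsh replicate 2, 905 without wing nub replicate 1 and 907 when only these 4 libraries were fitted. The call of Ubx was lost without wing tsh replicate 1.

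Within the haltere disc the same domain comparison gave higher levels of y (8.59 ± 0.20, 5549 ± 463 against 14.4 ± 1.58 CPM), rn (7.47 ± 0.18), Corin (7.26 ± 0.90), CCAP-R (7.22 ± 1.08), RacGAP84C (7.17 ± 0.38) and nub (6.64 ± 0.11) in nub cells. The neuropeptide receptor gene AstC-R2 was higher too (7.13 ± 0.95). A further pair of genes had 0 counts in haltere tsh cells, and they were at least 355-fold (lncRNA:CR44333) and 175-fold (CG5697) higher. With 1 count in tsh cells, meng was higher by a ratio of 560 (95% counting interval 100 to 22100), and with 2 counts CR10032 by a ratio of 422 (117 to 3480). Lower in nub cells were Cpr49Ac (-5.72 ± 0.52), hui (-5.50 ± 0.24), tio (-5.35 ± 0.15), opa (-5.08 ± 0.12), Drip (-5.07 ± 0.23) and tsh (-5.03 ± 0.20). Ubx was higher in nub than in tsh cells (1.79 ± 0.27). The calls of CCAP-R, meng and CG5697 were lost without either haltere nub library, and that of meng also without haltere tsh replicate 1.

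Of 15 distal genes 11 were higher in haltere nub cells, including dve (6.49 ± 0.15) and bs (1.63 ± 0.10), and 4 were lower, including salr (-2.56 ± 0.09), salm (-1.40 ± 0.09) and fj (-1.29 ± 0.10) (adjusted p = 1.96e-05, and adjusted p = 0.194 with an estimated correlation). Proximal genes were lower in 11 of 15 cases, such as caup (-3.34 ± 0.09) and ara (-2.92 ± 0.10) (adjusted p = 2.86e-13, and adjusted p = 0.292 with an estimated correlation). Hinge genes were lower in 8 of 10, such as grn (-4.06 ± 0.11) and drm (-4.90 ± 0.17) (adjusted p = 3.85e-08, and adjusted p = 0.247 with an estimated correlation). Notch genes were higher in 11 of 16 cases, with E(spl)m7-HLH at 2.22 ± 0.14 (adjusted p = 3.62e-08, and adjusted p = 0.338 with an estimated correlation). Sensory organ genes were higher in 7 of 12, with sca at 1.81 ± 0.09 (adjusted p = 3.8e-05, and adjusted p = 0.33 with an estimated correlation). Wnt genes were higher in 8 of 16 and lower in 2, with Wnt4 at 6.48 ± 0.20 and wg at 3.04 ± 0.14 (adjusted p = 0.000135, and adjusted p = 0.338 with an estimated correlation). Ribosomal protein genes were lower in 65 of 86 cases with a median of -0.50 (adjusted p = 2.02e-18, and adjusted p = 0.46 with an estimated correlation). With the gene span trend of all genes removed the median was -0.59 and 3 were called, as their median SE rose from 0.11 to 0.33. With the trend of genes over 5 CPM removed the median was -0.36 and 58 were called. Cell cycle genes were lower in 10 of 19, with stg at -0.91 ± 0.10 (adjusted p = 9.48e-05, and adjusted p = 0.428 with an estimated correlation). Removal of the gene span trend of all genes left 3 called lower, with a median SE of all genes of 0.27 against 0.16 before. Removal of the trend of genes over 5 CPM left 7. Camera also called the EGFR and compartment lists upward and the Hippo, tracheal and leg disc lists downward, with adjusted p between 0.33 and 0.609 with an estimated correlation.

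By the same test 2790 genes differed, 1115 higher and 1675 lower in nub cells, and 912 by at least 2-fold (476 higher and 436 lower). The count was 1534 with a gene span trend over all genes removed, 1456 without haltere tsh replicate 1, and 1515 and 1472 without haltere nub replicate 1 or 2.

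The interaction asked whether the haltere against wing difference was the same in both domains, with negative values where it was lower in nub than in tsh cells. The Doc genes went opposite ways: Doc2 was lower in haltere nub cells and higher in haltere tsh cells than in the wing (interaction -7.08 ± 0.19), as was Doc3 (-5.74 ± 0.22), and Doc1 (-5.78 ± 0.20) was lower in nub cells. The gene opa stood at 92.9 ± 2.09 CPM in wing nub, 98.2 ± 11.2 in wing tsh and 127.1 ± 6.88 in haltere tsh cells but at 3.76 ± 0.259 CPM in haltere nub cells (-5.00 ± 0.15). Cht5 (-3.83 ± 0.12), the peptidase gene Nep1 (-3.18 ± 0.15) and salr (-2.71 ± 0.13) had negative values too, and the RNA-binding protein gene cpo (4.74 ± 0.15) had a positive one, as did CG42741 and CG13272. The level of cpo was 221 ± 15.7 CPM in haltere nub cells against 16.5 ± 1.20 in wing nub cells. By edgeR's quasi-likelihood test 1727 genes had an adjusted p under the threshold, 820 positive and 907 negative. At 2-fold or more there were 751, of which 613 were positive and 138 negative. Low-level genes raised in wing tsh replicate 1 push the interaction upward, and the 2-fold counts were not recomputed without that library. The count was 3400 without wing tsh replicate 2, 711 without haltere tsh replicate 1, 781 and 695 without haltere nub replicate 1 or 2, and 803 without wing nub replicate 1.

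Calls of the disc comparison were shared between the domains in 32 genes higher in the haltere in both (11.3 expected from independent lists, Fisher's exact p = 3.26e-08) and 89 lower in both (33.9 expected, p = 4.12e-19), while 82 went opposite ways (40.0 expected). Opposite calls thus exceeded expectation too, so the excess was not only one of shared direction. Fisher's test treats genes as independent of each other, which they are not, here and for the domain comparison. The contrasts of each pair also came from the same fit with a shared spread per gene. Calls in them were thus not independent in advance. Across 11198 genes, which are not independent replicates, the log2 fold changes of nub and tsh cells had a Pearson's r of -0.17. Calls of the domain comparison were shared between the discs in 284 genes higher in nub cells in both (66.4 expected, Fisher's exact p = 3.77e-118) and 481 lower in both (131.9 expected, Fisher's exact p = 6.13e-185), with 150 opposite (187.6 expected). Across the same genes the log2 fold changes of the wing and haltere discs had a Pearson's r of 0.16 and a Spearman correlation of -0.03. Calls shared in the same direction numbered 46 for the disc comparison and 377 for the domain comparison at a 2-fold threshold. Without wing tsh replicate 2 the former was 263, and without haltere tsh replicate 1 it was 76.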

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

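The patterns weighed here were noticed in the data first, and the tests of the neighbours of y, of wing tsh replicate 2 and of the span trends were chosen only after related results had been seen. The other tests were set down before their own values were computed. The groups of 2 libraries are too small for a test of single outlying samples.

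The difference between haltere and wing itself differed between nub and tsh cells for 1727 genes by the interaction test. Of the 62 genes named in the comparisons of 2 groups, 39 had a called interaction, against 15.4% of all 11198 tested genes. The 62 were chosen for large fold changes in these same data, so a high share can follow from the choice alone. The 10 genes with the smallest adjusted p were Doc2 (-7.08), opa (-5.00), Cht5 (-3.83), cpo (4.74), Doc1 (-5.78), Doc3 (-5.74), CG42741 (3.71), CG13272 (4.89), Nep1 (-3.18) and salr (-2.71), all on the log2 scale, and of the identity genes Ubx (4.82) and nub (1.21) were called. Camera called 11 lists, none of them with an estimated correlation. Their median interactions were 3.72 for Hox genes, -0.64 for wing genes described as repressed in the haltere, 0.24 for Wnt, 1.01 for Notch, 1.52 for sensory organ, 1.32 for myoblast, 2.80 for fat body, -0.61 for cell cycle, 0.97 for stress, 0.32 for ecdysone and -0.56 for ribosomal protein genes. Without wing tsh replicate 1 the median was 0.90 for Hox genes and 0.71 for fat body genes.

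Wing tsh replicate 1 held reads in 83.3% of the 7458 genes that were under 0.5 CPM on average elsewhere. Expression in wing tsh cells is argued against by replicate 2: over 7435 genes chosen by the same level in the 6 libraries other than wing tsh, its median CPM divided by that of replicate 1 was 0, and 251 genes reached 0.5 CPM against 4797. Genomic DNA or other unspliced background may account for them. Over the 7458 genes reads followed gene span with a Spearman correlation of 0.61, across genes, against 0.20 to 0.43 in the other libraries. Exon lengths were not available, and span may stand in for them. In this library Myo81F, spanning 1965857 bp, had 9.56 CPM by library total, and TrpA1, spanning 10797 bp, had 8.41. The correlation therefore cannot tell unspliced reads from RNA of another tissue with long transcripts. Median density lay between 10.1 and 13.8 reads per kb of gene span on the X and the autosomes. It was 0.108 over 24 genes of the Y. That value cannot decide on DNA, since the counting rule and the handling of reads that match several genes are not given. RNA of another tissue stays open, since the tenth of genes with the most reads held 36.3% of them, between the bounds set for either answer.

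Ribosomal protein genes were lower in haltere nub cells. Thinning every library to the same total left the median at -0.56. Reads were drawn at random, which keeps the expected share of each gene, so this cannot decide whether depth played a part. A bias against short, abundant genes is a candidate explanation, since the genes differed by only -0.06 from others of the same span and level, which had a median of -0.51. Span includes introns, and exon lengths were not available. The match therefore cannot tell such a bias from a difference shared by abundant genes. A span trend alone left more of the lowering: with the trend of genes over 5 CPM removed the median was -0.42 and 61 of 86 genes were called lower. With the trend of all genes removed the median was -0.67, yet 8 were called, since the median SE rose from 0.11 to 0.33. A separate sequencing batch of the 2 haltere nub libraries, whose smaller total was 5.22 times the largest other, cannot be told apart from their group, and a difference between the tissues stays open as well.

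The pigmentation gene y stood at 5549 CPM in haltere and 6468 CPM in wing nub cells. A pigmentation programme is argued against, since 12 other pigmentation genes had a median of -1.64 in the wing and -1.39 in the haltere disc, nub against tsh. Many of the single values were not called, and no member was called higher in nub cells of either disc. Activity spread over the neighbourhood is argued against in the wing disc, where the 10 nearest tested genes had a median of -0.37. The nearest of them, ac, sc and CG32816, lay at 0.16, -0.05 and 1.53 there. No median was computed without wing tsh replicate 1, whose raised low-level genes would lower such values. In the haltere disc the median of the 10 genes was 1.38. Yet y rose no more there (8.59 ± 0.20) than in the wing disc (8.79 ± 0.20), so spread activity cannot account for the rise in both discs. Sequence carried by the driver line cannot be told apart from expression of the gene, since y differed by only -0.22 between haltere and wing nub cells, which both would allow.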

How the results depend on the processing

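The span corrections and the thinning were chosen after seeing the data, and the second span correction after the result of the first. Counts of genes called stayed within 1.5 times of the main count under RLE size factors, both filters, the replicate block, removal of mitochondrial and rRNA genes, thinning and the span trend of genes over 5 CPM. They moved at a 2-fold threshold, to 709, 160, 730, 912 and 751 in the order of the report, with shared disc calls at 46 and shared domain calls at 377. DESeq2 called 720 genes between haltere and wing tsh cells. Fitting only the compared groups gave 3952 for haltere against wing in nub cells, 241 in tsh cells and 907 for nub against tsh in the wing disc, with fewer samples behind the spread. This setting leaves the interaction as it is. Removing the span trend of all genes gave 1525 for haltere against wing in nub cells, 1534 for nub against tsh in the haltere disc and 491 shared domain calls, against 2473, 2687 and 854 with the trend of genes over 5 CPM. The cause was not tested. The first correction also shifted the median of all genes by up to -0.380 (interaction), raised the median SE of all genes from 0.16 to 0.27 (haltere against wing, nub cells) and turned 8 values: Antp -0.14, ct -0.10, shn -0.38, pnt -0.15, futsch -0.19 and br -0.06 in the interaction, fng 0.05 (haltere against wing, tsh cells) and ds 0.04 (nub against tsh, wing disc). The second turned none of them.

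Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave 1176 to 1863 genes for haltere against wing in nub cells, 177 to 1621 in tsh cells, 905 to 2718 for nub against tsh in the wing disc, 1456 to 1940 in the haltere disc and 695 to 3400 for the interaction. Shared disc calls ranged from 76 to 263 and shared domain calls from 589 to 913. The highest gene counts came without wing tsh replicate 2 in the 3 contrasts with that group. With the filter applied again, which tested 11299 to 14934 genes, these ranges were 1438 to 2054, 255 to 3308, 1323 to 4657, 1784 to 2382 and 835 to 4255, and 6 list values reversed in place of 2: the distal, BMP, Notch and ecdysone lists for haltere against wing in tsh cells and the ecdysone list for nub against tsh in the wing disc, all without wing tsh replicate 2, and the ribosomal protein list for nub against tsh in the wing disc without replicate 1. The 2 in the fixed gene set were the BMP list without wing tsh replicate 2 (median 0.06, haltere against wing, tsh cells) and the ribosomal protein list without wing tsh replicate 1 (median -0.08, against 0.27 without replicate 2, nub against tsh, wing disc). The 4 compared-group fits filtered again gave 3891, 299, 1100 and 3941.

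Shares of higher calls moved most at a 2-fold threshold, to 71.4%, 13.8%, 22.5%, 52.2% and 81.6% in the order of the report, against 41.7%, 31.8%, 43.1%, 40.0% and 47.5%. In the contrasts with wing tsh cells, raised low-level genes of wing tsh replicate 1 push towards these shares. With no low-count filter, the medians of all genes were 0.06, -0.257, -0.314, 0.112 and 0.455 in the same order. They also moved by over 10 points under the stricter filter for haltere against wing in nub cells (54.4%), for nub against tsh in the haltere disc (50.7%) and for the interaction (59.7%), under DESeq2 for the interaction (61.4%), and with the span trend of all genes removed for haltere against wing in tsh cells (44.3%) and nub against tsh in the wing disc (53.8%). With the trend of genes over 5 CPM removed the tsh share was 44.5%. In the interaction 54 ribosomal protein genes were called lower, and 6 with the span trend of all genes removed, where their median went from -0.56 to -0.87 and their median SE from 0.16 to 0.47. With the trend of genes over 5 CPM removed 26 were called, at a median of -0.38 and a median SE of 0.14. Of 59 list calls 0 held with an estimated correlation, and fry shared 48. Of 6471 recomputed values of named genes and list members 6089 stayed on their side of the threshold, called or not, 367 lost a call, 7 gained one and 8 turned. The main fit was unpaired. Deviations of same-numbered libraries correlated between -0.25 and 0.11, which leaves pairing open. The replicate block gave 2476, 315, 1438, 2696 and 1562 genes. One read in the shallowest library is 0.0662 CPM.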

Other observations

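Both sets of genes below were chosen only after their values had been seen. Cuticle genes were grouped by symbol. Of 3 Ccp84A genes 2 were higher in haltere than wing nub cells and 2 were lower in haltere than wing tsh cells. Of 34 tested Cpr genes 5 were higher and 5 lower in haltere nub cells, and 2 were higher and 2 lower in haltere tsh cells. Cpr49Ac was among the most abundant, at 4107 ± 346 CPM in haltere tsh and 3329 ± 688 in wing tsh cells (SD, n = 2), against 77.8 ± 31.2 and 22.4 ± 12.2 in nub cells. Among chitinase and Idgf genes 6 of 11 were lower and 2 higher in nub than in tsh cells of the wing disc, and 5 lower and 1 higher in the haltere disc, with Idgf4 at 945 ± 18.2 CPM in haltere tsh and 85.5 ± 8.26 in haltere nub cells.

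Of the 10 nearest tested neighbours of y, 5 were called higher in haltere nub than in haltere tsh cells: ac (log2 fold change 1.55), sc (1.20), CG32816 (5.92), and Or1a and CG12470, which had 3 and 6 counts in haltere tsh cells. CG13375 lay at 4.07 without a call, and the 4 farther genes lay between -0.38 and 0.76, none called. In the wing disc only CG3777 was called (-0.71), and the values were 0.16 for ac, -0.05 for sc, 1.53 for CG32816, -2.18 for Or1a and -3.23 for CG13375, with CG12470 lower on 3 counts in wing nub cells.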
